A study of Homo sapiens with 36 samples.

How the data were processed

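Total RNA was sequenced from cardiomyocytes made from the human induced pluripotent stem cell line 201B7, which carries the FUCCI reporter of cell cycle position. The 36 libraries fall into 3 experiments, each with its own table. In the FUCCI experiment, day 20 cardiomyocytes were separated into Red (Kusabira-Orange positive, Azami-Green negative), White (negative for both) and Green (Azami-Green positive, Kusabira-Orange negative) cells, with 2 libraries per group. In the sorted experiment, embryoid bodies received the retinoic acid receptor agonist Am80 or its solvent DMSO from day 18, and cardiomyocytes were sorted on day 20, with 3 libraries per group. In the siRNA experiment, purified cardiomyocytes were transfected on day 17 with a control siRNA (siNC), siRARA, siRARB or both, were given Am80 or DMSO from day 18 and were harvested on day 20, with 3 libraries in each of 8 groups. The labels give the purification as positive sorting for CD172a/b and negative sorting for CD31, CD49a, CD90 and CD140b. They also say that cells of the siRNA experiment were sorted after siRNA treatment, so the order of sorting and transfection is stated in more than 1 way.

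Groups and replicate numbers were taken from the sample titles, which are also the column names of the tables. For the 6 libraries of the sorted experiment the title and the treatment tag name opposite treatments. These libraries are therefore called "titled Am80" and "titled DMSO", and the groups follow the titles. The labels put the replicate number into an experiment tag, so a number marks a shared experiment and pairs the libraries across groups. Nothing in the labels says whether the replicates came from separate differentiations. If they did not, the p-values measure only the spread between these libraries, which may then be technical.

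Per the submitters' processing notes, the tools used were bcl2fastq 2.17.14, cutadapt 1.15, Bowtie2 2.2.5, STAR 2.5.3a, HTSeq 0.9.1, R 3.6.1 and DESeq2 1.26.0, with the genome build GRCh38. The annotation is not given in the sources used here. The labels' protocols name stranded total RNA libraries with removal of ribosomal RNA. The deposited values are gene-level signal values, namely read counts divided by DESeq2 size factors, per the file headers, and each table was normalised on its own, so levels are compared only within a table. The tables hold 33055 (FUCCI), 30634 (sorted) and 36400 (siRNA) gene names. Each holds 4 duplicated names, and 26, 26 and 27 names have been turned into dates. None of these is named in the text. Whole reads were recovered by dividing each library's values by the value of 1 read, and 100% of the values came out whole within 0.001 of a read. The recovered depth was 27348929 to 34799828 reads in the 6 FUCCI libraries, 19780381 to 27998911 in the 6 sorted libraries and 18473921 to 34466762 in the 24 siRNA libraries. Mitochondrially encoded genes took 0.392 to 0.809%, 0.426 to 0.700% and 0.393 to 0.655% of the reads.

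The tests, gene lists and alternatives were fixed before the data were examined, unless stated otherwise. Each experiment was fitted with limma 3.58.1 (R 4.3.3, mean-variance trend) on log2(normalised count + 1) over all its libraries, for genes with a mean of at least 10: 18406, 16763 and 16304 genes. A log2 change is on that scale, which understates the change of low genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 are said to have risen or fallen, and adjusted p-values of genes are from limma. Of the tested names, 97.88%, 98% and 98.18% are gene names in GENCODE v29, which is on the same build and gave the coordinates and 3′ untranslated regions (UTRs). Each of 30 hand-written lists of 12 to 57 genes was tested with camera in limma if at least 5 members were tested, with a preset correlation of 0.01 and adjustment over the lists of a comparison. The lists were retinoic acid targets, retinoid synthesis and receptors, anterior HOX genes, S phase, G2 and M phase, G1 cyclins and E2F, CDK inhibitors and quiescence, replication-dependent histones, sarcomere, atrial, ventricular, calcium handling and ion channels, fatty acid oxidation, glycolysis, oxidative phosphorylation, mitochondrially encoded, cholesterol synthesis, p53 targets, integrated stress and unfolded protein response, immediate early and heat shock, interferon response, YAP targets, hypoxia targets, fibroblast and matrix, smooth muscle and pericyte, endothelial, epicardial, pluripotent, endoderm and liver, and neural. Of 407 list tests, 140 passed. With the correlation estimated from the residuals 1 passed, the retinoic acid targets with Am80 under siRARB, and 6 did with an estimated correlation and the replicate number as a block. An adjusted p "with an estimated correlation" is given where a list is described. In the FUCCI experiment no list passed with it, not even G2 and M phase, all 57 genes of which rose in Green against Red. The correlation is estimated there from 2 libraries per group. Failing with it is therefore not evidence that a list did not move.

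Sets of genes called in the FUCCI or the sorted experiment were carried into the other experiments and tested there in the same way. They are the Green-high and Red-high genes (adjusted p below 0.05 and a log2 change beyond 1 between Green and Red) and the Am80-raised and Am80-lowered genes of the sorted experiment. Named genes are the 8 highest and 8 lowest log2 changes among passing genes with a mean of at least 100, a proper symbol and no overlap between the libraries, the 4 members of each list with the smallest p, and 22 genes fixed in advance. Genes outside this rule are said to have been chosen after their values were seen. The differences of the Am80 effect between siRNAs are interaction contrasts. Because the 3 knockdown comparisons share the siNC libraries, overlaps between them are not given.

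Libraries with the same number deviated from their group means together. The correlation of the deviations was 0.388 to 0.546 over the 6 such pairs of the FUCCI experiment, 0.530 to 0.753 over the 3 pairs of the sorted experiment and 0.330 to 0.775 over the 84 pairs of the siRNA experiment, where other pairs gave -0.632 to 0.122. With 2 libraries per FUCCI group, the other pairs give the same sizes with the opposite sign by construction. The fit without the replicate number stayed the main one as planned, since the labels state no model with that number. The value "with the block" is the fit with that number as a block. The main fit counts the spread shared by a number as error. It called fewer genes in most comparisons, such as 260 against 1707 with the block for Am80 under siNC. A gene or list that did not pass in the main fit is therefore not shown to be unchanged.

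The fit was tested on simulated counts with 200 changed genes. At a log2 change of 1 and of 2 it recovered 10% and 52% of the changed genes for Green against Red, 27% and 84% for the sorted experiment, 61% and 85% for Am80 under siNC, and 38% and 76% for the difference of the Am80 effect under both siRNAs. Of the calls, 12 of 74, 12 of 123, 8 of 154 and 5 of 119 were genes that had not been changed. The simulated libraries had no effect shared by a replicate number. For Green against Red and the sorted experiment the real fits called 4560 and 1671 genes, which makes the adjusted threshold less strict. The recovered shares therefore describe the simulation and need not hold for the real data. The alternatives were a pseudocount of 8, no filter, a minimum mean of 50, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, equal library totals, the block, each library left out, and, in the siRNA experiment, only the libraries of the groups compared. A scan of 3′ UTRs for short sequences shared by genes that moved under an siRNA was added after the knockdown counts were seen. It used 11683 genes with a mean of at least 50 and an annotated UTR of at least 50 bases, which is 91.5% of the 12770 genes of that level, and 15639 heptamers present in at least 100 genes. On permuted data with a planted shift it ranked the planted heptamer first in 20 of 20 runs. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.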

Results

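Gene expression was measured by sequencing total RNA from cardiomyocytes derived from the human induced pluripotent stem cell line 201B7, whose FUCCI reporter shows by colour where a cell is in its cycle. The FUCCI experiment holds 2 libraries each of Red, White and Green cells. The sorted experiment holds 3 libraries titled Am80 and 3 titled DMSO. Am80 (tamibarotene) is a synthetic agonist of the retinoic acid receptors. The siRNA experiment holds 3 libraries for each of siNC, siRARA, siRARB and both receptor siRNAs, in DMSO and in Am80. Depth was 27348929 to 34799828 reads per library in the FUCCI experiment, 19780381 to 27998911 in the sorted experiment and 18473921 to 34466762 in the siRNA experiment. Values are normalised read counts, given as mean ± SD. In GENCODE v29 on GRCh38, RARA lies on chromosome 17 (40309192 to 40357643), RARB on chromosome 3 (25174332 to 25597932) and CYP26A1 on chromosome 10 (93073475 to 93077890). CYP26B1 lies on chromosome 2 (72129238 to 72148038), DHRS3 on chromosome 1 (12567910 to 12617731) and MEGF6 on chromosome 1 (3489920 to 3611495).

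Green and Red cells were compared to ask how the transcriptome of cells in S, G2 or M phase differs from that of cells in G1 or out of the cycle. Mitotic genes were far higher in Green (n = 2) than in Red (n = 2). KIF20A, a kinesin of cell division, stood at 16500 ± 4386 against 18.5 ± 13.5 (log2 change 9.90), and UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, at 10250 ± 2561 against 15.4 ± 0.677. MKI67, the proliferation marker, rose from 68.1 ± 9.22 to 15070 ± 2803 (log2 change 7.76). TOP2A, a topoisomerase of replicating cells, rose from 199 ± 61.9 to 87900 ± 17200, and CCNB1, the mitotic cyclin B1, from 168 ± 5.47 to 16230 ± 3580. All 57 G2 and M phase genes rose (57 adjusted over the list alone), as did all 30 replication-dependent histone genes (30), with HIST1H3G from 17.9 ± 2.83 to 13350 ± 2684. Of 43 S phase genes 38 rose and 1 fell (39 and 1 adjusted over the list alone). RRM2, a subunit of ribonucleotide reductase, rose from 6.22 ± 1.76 to 1660 ± 42.1. Of 16 G1 cyclin and E2F genes 8 rose (8, with 1 that fell, adjusted over the list alone), E2F2 from 3.82 ± 1.19 to 290 ± 112. The adjusted p of these 4 lists was 4.2e-48, 6.8e-29, 2.7e-23 and 0.00062, and 0.35, 0.35, 0.35 and 0.56 with an estimated correlation.

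Genes of the contractile apparatus were lower in Green (n = 2) than in Red (n = 2): 20 of 27 sarcomere genes fell and none rose (25 adjusted over the list alone; median log2 change -1.70). MYL2, the ventricular myosin light chain, fell from 3069 ± 522 to 692 ± 14.5, TCAP, the titin cap protein of the Z disc, from 1995 ± 538 to 185 ± 28.8. MYL7, the atrial light chain, fell from 47630 ± 3804 to 12600 ± 4620, and TNNT2, cardiac troponin T, from 53220 ± 6812 to 11180 ± 5527. Of 22 calcium handling and ion channel genes 15 fell and 1 rose (20 and 1 adjusted over the list alone), SRL, a protein of the sarcoplasmic reticulum, from 2425 ± 128 to 624 ± 212. Fatty acid oxidation genes (13 of 25 fell, 14 adjusted over the list alone), oxidative phosphorylation genes (11 of 36, 17) and mitochondrially encoded genes (5 of 13, 5) were lower as lists. COX7A1, a muscle form of a respiratory chain subunit, fell from 583 ± 69.4 to 96.1 ± 28.1. Glycolysis (3 of 19, 3), cholesterol synthesis (8 of 21, 9) and ventricular genes (3 of 14 with 1 that rose, 3 and 1) were lower as well. The adjusted p was 9.2e-11 for sarcomere, 2.7e-07 for calcium handling and at most 0.017 for these 6 other lists, and 0.52 to 0.56 for all 8 with an estimated correlation.

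Genes of other cell types moved with the same comparison. In the endoderm and liver list 10 of 14 genes fell and 4 rose, and the counts were the same adjusted over the list alone. The list was lower in Green (median log2 change -4.46, adjusted p = 0.014, and 0.56 with an estimated correlation). SERPINA1, the plasma protease inhibitor alpha-1-antitrypsin, fell from 7661 ± 1345 in Red (n = 2) to 176 ± 52.1 in Green (n = 2), and APOB, the main protein of low-density lipoprotein, from 1927 ± 474 to 81.6 ± 23.6. FOXA1, an endoderm transcription factor, rose from 22.5 ± 3.76 to 599 ± 210. AFP, alpha-fetoprotein, chosen after its values were seen, fell from 21040 ± 4578 to 630 ± 361. The epithelial adhesion genes CDH1 (607 ± 189 to 9766 ± 3363) and EPCAM (684 ± 232 to 4241 ± 1481), also chosen after their values were seen, rose. Epicardial (5 of 10 rose, 5 adjusted over the list alone), pluripotent (4 of 9, 5) and YAP target genes (9 of 18 with 1 that fell, 9 and 1) were higher as lists. DNMT3B, a DNA methyltransferase of pluripotent cells, rose from 150 ± 6.24 to 619 ± 39.9 and CTGF, a YAP target, from 8095 ± 163 to 32580 ± 674. The p53 targets (6 of 21 rose, 6) and the integrated stress and unfolded protein response (8 of 19, 10 with 1 that fell) were higher too, with ATF3, a stress-induced transcription factor, at 14940 ± 1938 against 4006 ± 142. The adjusted p of these 5 lists lay between 0.008 and 0.026, and was 0.56 with an estimated correlation. The remaining 11 lists did not pass. Among them were the retinoic acid targets (5 of 16 rose and 3 fell, 5 and 5 adjusted over the list alone, adjusted p = 0.71) and the retinoid synthesis and receptor genes (2 of 14 rose and 2 fell, 2 and 6 adjusted over the list alone, adjusted p = 0.32). The hypoxia targets (2 of 15 rose and 2 fell, adjusted p = 0.99), the interferon response (3 of 16 rose, adjusted p = 0.35) and the smooth muscle and pericyte genes (1 of 12 rose and 1 fell, adjusted p = 0.35) had the same counts adjusted over the list alone. With the block, 3 of the 11 passed: atrial genes (adjusted p = 0.15 without and 0.028 with it), CDK inhibitors (0.067 and 0.047) and immediate early and heat shock genes (0.055 and 0.009).

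In total 2661 genes rose and 1899 fell of 18406 tested in Green against Red (4170 and 3745 with the block). Without Red replicate 1 the counts were 1133 and 240, and without Green replicate 1 they were 1133 and 514. Without Red replicate 2 they were 871 and 186, and TNNT2 (log2 change -2.21) and EPCAM (2.28) no longer passed.

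**Figure D1:**
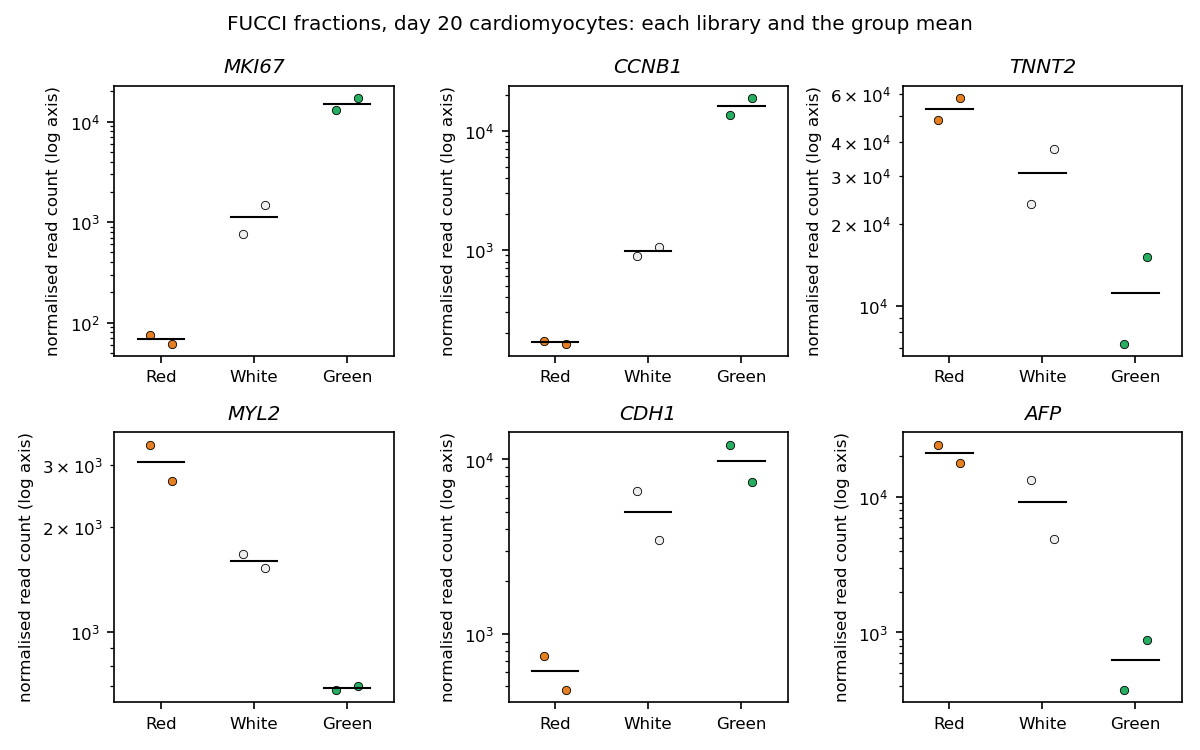
Normalised read counts on a log axis for 6 genes in the Red, White and Green libraries, where points are libraries (2 per group) and lines are group means. The means of MKI67, CCNB1 and CDH1 are lowest in Red and highest in Green, and those of TNNT2, MYL2 and AFP are highest in Red and lowest in Green.

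White cells, which lacked both colours, were compared with Red cells to place them in the cycle. They held intermediate levels of cell cycle genes. MKI67 stood at 1118 ± 497 (n = 2) against 68.1 ± 9.22 in Red (n = 2), and TOP2A at 3807 ± 1183 against 199 ± 61.9. CCNB1 stood at 978 ± 119 against 168 ± 5.47 and RRM2 at 141 ± 20.9 against 6.22 ± 1.76, and all 4 rose. Of the G2 and M phase genes 38 of 57 rose (45 adjusted over the list alone), of the histone genes 25 of 30 (28), of the S phase genes 14 of 43 (25) and of the G1 cyclin and E2F genes 2 of 16 (4). The adjusted p of these 4 lists was 5.6e-46, 1.4e-35, 6.4e-15 and 0.0062, and 0.37, 0.37, 0.37 and 0.60 with an estimated correlation. The sarcomere list was lower in White (1 of 27 fell, and 1 adjusted over the list alone, median log2 change -0.82, adjusted p = 2.0e-07). So were the calcium handling, fatty acid oxidation, oxidative phosphorylation and cholesterol synthesis lists, in which no gene passed, also adjusted over the list alone. Their adjusted p was at most 0.00025, and that of all 5 was 0.37 to 0.71 with an estimated correlation. The stress response (1 of 19 rose, 1 adjusted over the list alone), immediate early (1 of 17, 4), YAP target (2 of 18, 7 with 1 that fell), epicardial (1 of 10, 5) and pluripotent lists (0 of 9, 4) were higher. Their adjusted p was between 0.0016 and 0.011, and 0.60 to 0.63 with an estimated correlation. Glycolysis (adjusted p = 0.17, and 0.014 with the block) and the fibroblast list (0.32 and 0.016) passed only with the block. Epithelial CDH1, at 5018 ± 2229 in White, and EPCAM, at 2752 ± 1148 and chosen after its values were seen, lay between the means of Red and Green. EPCAM did not pass against Red (adjusted p = 0.082, and 4.4e-07 with the block).

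In White against Red 321 genes rose and 2 fell (1760 and 830 with the block, and 1099 in total with DESeq2). The 2 that fell were MYL2 (log2 change -0.93) and PCDH9, a protocadherin (-1.10). Neither passed when any of the 4 libraries was left out, with log2 changes of -1.10 to -0.756 for MYL2 and -1.32 to -0.885 for PCDH9, nor with equal library totals. Without Red replicate 1, White replicate 1 and Red replicate 2 the counts that rose were 175, 137 and 109, and none fell, and without White replicate 2 the counts were 277 and 1.

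Green was compared with White to separate cells in S, G2 or M phase from the double-negative cells. CDK1, the mitotic kinase, rose from 774 ± 180 (n = 2) to 22250 ± 5136 (n = 2). HJURP, a chaperone of centromeric chromatin, rose from 204 ± 0.0548 to 6025 ± 1233, and PCNA, the replication clamp, from 628 ± 56.8 to 2800 ± 226. All 57 G2 and M phase genes rose (57 adjusted over the list alone), as did 27 of 30 histone genes (30) and 31 of 43 S phase genes, with 1 that fell (39 and 1). So did 7 of 16 G1 cyclin and E2F genes (7) and 2 of 15 CDK inhibitor and quiescence genes (6). Among the latter was CDKN2C, an inhibitor of the G1 kinases, which rose from 12.6 ± 4.35 to 394 ± 120. SERPINA1 fell from 3563 ± 2285 to 176 ± 52.1 and APOA2, an apolipoprotein made by liver, from 330 ± 2.25 to 32.0 ± 4.77. They were among the 6 of 14 endoderm and liver genes that fell (8, with 1 that rose, adjusted over the list alone, adjusted p = 0.00046). The sarcomere list was lower (2 of 27 fell, 13 adjusted over the list alone, adjusted p = 1.3e-09), with MYL2 falling from 1600 ± 102 to 692 ± 14.5. Troponin T, TNNT2, stood at 11180 ± 5527 against 30790 ± 9958 and did not pass (adjusted p = 0.083, and 6.5e-05 with the block). The calcium handling, ventricular, fatty acid oxidation, glycolysis, oxidative phosphorylation, mitochondrially encoded and cholesterol synthesis lists were also lower, and the stress response list was higher (adjusted p of at most 0.036). With an estimated correlation the adjusted p of the 15 lists was 0.23 for the S phase, G2 and M phase and histone lists and 0.58 for the others. The atrial (adjusted p = 0.077, and 0.0086 with the block), p53 target (0.051 and 0.026) and YAP target lists (0.098 and 0.012) passed only with the block.

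In Green against White 774 genes rose and 224 fell (2021 and 1667 with the block, 1960 in total with DESeq2, and 667 and 371 with equal library totals). Without White replicate 1 the counts were 555 and 46, without White replicate 2 they were 522 and 82, and without Green replicate 2 they were 413 and 217. Without Green replicate 1 they were 418 and 49, and MYL2 (log2 change -1.18) no longer passed.

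The sorted experiment asked what Am80 does to cardiomyocytes inside embryoid bodies. In the libraries titled Am80 (n = 3) the targets of the retinoic acid receptors were higher than in those titled DMSO (n = 3). Of 16 tested 14 rose (14 adjusted over the list alone, adjusted p = 2.7e-18, and 0.095 with an estimated correlation). CYP26A1 and CYP26B1, the enzymes that clear retinoic acid, rose from 6.70 ± 4.84 to 75920 ± 22280 (log2 change 13.43) and from 10.3 ± 8.2 to 25140 ± 7285. DHRS3, a retinaldehyde reductase, rose from 46.0 ± 4.36 to 11430 ± 949.8, LRAT, which stores retinol as esters, from 50.9 ± 31.5 to 19230 ± 6733, and the receptor gene RARB from 1478 ± 320 to 9803 ± 831. All 5 anterior HOX genes tested rose (5 adjusted over the list alone, adjusted p = 8.7e-07, and 0.12 with an estimated correlation). HOXB2 rose from 478 ± 38.9 to 1425 ± 193 and HOXB4 from 112 ± 6.79 to 341 ± 42.1.

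Cell cycle genes were also higher with Am80. Of 43 S phase genes 33 rose (39 adjusted over the list alone), and of 29 histone genes 23 (28). Of 16 G1 cyclin and E2F genes 8 rose and 1 fell (9 and 1), and of 57 G2 and M phase genes 5 rose (25, and 55 with the block). CCND2, cyclin D2, rose from 11530 ± 1861 (n = 3) to 67890 ± 21920 (n = 3), CCNE2, cyclin E2, from 21.3 ± 6.75 to 261 ± 134. DTL, which directs licensing factors to degradation, rose from 257 ± 7.42 to 1405 ± 216, and CDC25A, a phosphatase that activates cyclin-dependent kinases, from 254 ± 13.3 to 883 ± 101. MKI67 (3912 ± 2340 against 1503 ± 586) and CCNB1 (2765 ± 2250 against 1415 ± 778) did not pass (adjusted p = 0.11 and 0.48) and did with the block (1.0e-05 and 0.00047). CDK inhibitor and quiescence genes (4 of 15 rose and 1 fell, 4 and 1 adjusted over the list alone) were higher as a list, with BTG2, an antiproliferative gene, from 2248 ± 404 to 10540 ± 2164. The p53 targets (4 of 21 rose, 4) and the epicardial genes (1 of 6 rose, 3) were higher as lists. The adjusted p of these 7 lists ran from 5.9e-29 for S phase to 0.013 for the CDK inhibitor and epicardial lists, and was 0.095 to 0.43 with an estimated correlation.

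Muscle genes were lower with Am80. Of 27 sarcomere genes 8 fell (12, with 1 that rose, adjusted over the list alone). MYL2 fell from 595 ± 84.5 (n = 3) to 124 ± 34.1 (n = 3) and TNNI1, slow skeletal troponin I of fetal heart, from 17070 ± 2132 to 8493 ± 882. Of 20 calcium handling and ion channel genes 7 fell (10 adjusted over the list alone). KCND3, a potassium channel, fell from 96.0 ± 17.0 to 16.4 ± 1.56. Smooth muscle genes (3 of 12 fell, 4 adjusted over the list alone) were lower as a list, with MYH11, smooth muscle myosin, falling from 3365 ± 1393 to 484 ± 248. So were YAP targets (1 of 18, 6) and oxidative phosphorylation genes (1 of 36, 0). Adjusted p-values of these 5 lists ran from 8.7e-07 for calcium handling to 0.0046, and were 0.17 to 0.77 with an estimated correlation. The atrial list did not pass (2 of 15 rose and 1 fell, 2 and 1 adjusted over the list alone, adjusted p = 0.74), and its members went both ways. KCNJ5, an atrial potassium channel subunit, rose from 1115 ± 107 to 3483 ± 72.7. GJA5, connexin 40, rose from 17.6 ± 7.15 to 157 ± 51.1, and KCNA5, the atrial ultrarapid potassium channel, fell from 258 ± 72.7 to 28.6 ± 15.1. Fatty acid oxidation passed only with the block (adjusted p = 0.051, and 0.0045 with it).

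In the sorted experiment 1032 genes were higher and 639 lower in the libraries titled Am80 (3074 and 2934 with the block), of 16763 tested. Treatment tag and title disagree for all 6 libraries. Under the titles 100 genes rose and 32 fell both here and with Am80 under siNC, and 0 passed in opposite directions (with the block 599 and 478 shared, and 38 and 40 opposite), which argues against exchanged titles. The counts were 557 and 210 without DMSO replicate 2, 527 and 249 without Am80 replicate 2, 576 and 243 without DMSO replicate 3, and 676 and 318 without Am80 replicate 3.

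The sets of genes called in 1 experiment were tested in the other, which shares no library with it. The 1480 Green-high genes tested in the sorted experiment were higher with Am80 (394 rose and 18 fell, median log2 change 0.56), and the 1017 Red-high genes were lower (159 fell and 40 rose, median -0.38). The adjusted p was 5.2e-23 and 1.8e-10, and 0.047 for both with an estimated correlation (0.10 and 0.093 with the block as well). In Green against Red, 455 of 965 Am80-raised genes rose and 66 fell (median 0.81), and 221 of 637 Am80-lowered genes fell and 31 rose (median -0.67). The adjusted p was 1.3e-15 and 5.2e-13, and 0.068 and 0.079 with an estimated correlation.

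The siRNA experiment asked whether plated, purified cardiomyocytes respond to Am80 and which receptor the response needs. Under siNC (n = 3 per treatment) Am80 raised CYP26A1 from 5.699 ± 3.998 to 4761 ± 2343 (log2 change 9.51) and CYP26B1 from 9.87 ± 2.93 to 2560 ± 1359. DHRS3 rose from 120 ± 15.7 to 5714 ± 1717, LRAT from 36.9 ± 5.17 to 10790 ± 4993 and RARB from 366 ± 55.2 to 2413 ± 344. IGFBP6, an IGF-binding protein, rose from 58.1 ± 29.7 to 919 ± 271, and MEGF6, an EGF-repeat gene chosen after its values were seen, rose from 324 ± 80.7 to 2513 ± 784. Of 18 retinoic acid targets 7 rose (10 adjusted over the list alone), with a median log2 change of 1.46 (adjusted p = 4.1e-18, and 0.065 with an estimated correlation, or 0.0026 with the block as well). The S phase list was higher (median 0.43), and so were the G2 and M phase (0.48), the histone (0.42) and the G1 cyclin and E2F lists (0.29). In these 1 of 43, 0 of 57, 0 of 28 and 1 of 16 genes rose. Adjusted over the list alone 13, 0, 15 and 2 rose and 1 of the last list fell, and with the block 17 of the G2 and M phase genes rose. In the order of their numbers the pairs of libraries had S phase medians of 0.236, 0.327 and 0.766. Their G2 and M phase medians were 0.179, 0.350 and 0.910. MKI67 stood at 2675 ± 153 against 1770 ± 406 and did not pass (adjusted p = 0.32, and 0.021 with the block). The sarcomere list was lower (2 of 25 fell, 5 adjusted over the list alone, median -0.52). ACTN2, the alpha-actinin of the Z disc, fell from 5511 ± 894 to 2596 ± 654 and NEBL, a Z disc protein, from 22240 ± 1797 to 10590 ± 2276. The calcium handling (0 of 21 fell, median -0.43), smooth muscle (0 of 12, -0.40) and neural lists (1 of 5, -0.63) were lower too, with 0, 2 and 1 genes that fell adjusted over the list alone. CDKN2B, a G1 kinase inhibitor, rose from 200 ± 43.0 to 1134 ± 189. For these 8 lists the adjusted p ran from 2.8e-15 for S phase to 0.012 for the neural list, and was 0.14 to 0.52 with an estimated correlation.

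Under siNC 179 genes rose and 81 fell of 16304 tested (925 and 782 with the block, 503 in total with DESeq2). A fit to these 6 libraries alone called 25 genes, without NEBL and ACTN2, and the counts were 100 and 24 without DMSO replicate 2, 96 and 23 without Am80 replicate 2 and 143 and 48 without Am80 replicate 3. Of the genes tested in both experiments, 100 rose with Am80 both under siNC and in the sorted experiment where 10.8 would be shared by chance, and 32 fell in both where 3.06 would be.

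With either receptor siRNA fewer genes passed with Am80 than under siNC. Under siRARA (n = 3 per treatment) 15 rose and 0 fell. DHRS3 rose from 212 ± 85.9 to 2842 ± 1260, IGFBP6 from 74.8 ± 26.1 to 578 ± 188 and MEGF6 from 340 ± 45.4 to 1557 ± 524. CYP26A1 (820 ± 819 against 12.8 ± 8.23) and RARB (1578 ± 574 against 504 ± 110) did not pass and did with the block (adjusted p = 0.0061 and 0.00035). Under siRARB (n = 3) 33 rose and 0 fell. DHRS3 rose there from 122 ± 34.6 to 2891 ± 741, IGFBP6 from 55.9 ± 8.27 to 580 ± 106 and MEGF6 from 297 ± 46.8 to 1480 ± 399. CYP26A1 stood at 383 ± 483 against 5.26 ± 2.74 (adjusted p = 0.29, and 0.0046 with the block). Under both siRNAs (n = 3) limma called 0 genes, with 210 at an unadjusted p under 0.05, 0 with edgeR, 2 with DESeq2 and 1 without the filter. The 210 are fewer than the share of 0.05 of 16304 tested genes that chance alone would give, and with the block 885 lay there. There DHRS3 stood at 708 ± 458 against 194 ± 69.9, RARB at 479 ± 157 against 224 ± 97.2, CYP26A1 at 322 ± 402 against 8.02 ± 5.41 and MEGF6, chosen after its values were seen, at 482 ± 79.0 against 312 ± 60.7.

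The retinoic acid targets were higher with Am80 under each siRNA, with medians of 0.79, 0.84 and 0.38 log2 under siRARA, siRARB and both. Of 18 genes 1, 2 and 0 rose (6, 8 and 4 adjusted over the list alone). The adjusted p was 1.1e-09, 1.9e-21 and 5.2e-09, and 0.25, 0.033 and 0.27 with an estimated correlation (0.024, 0.00057 and 0.018 with the block as well). In the order of their numbers the pairs of libraries under siRARA had medians of 0.102, 0.976 and 0.640 for these targets. Under siRARA the S phase list was higher (0 of 43 rose, also adjusted over the list alone, median 0.15) and the neural list lower (0 of 5 fell, 1 adjusted over the list alone, median -0.45). Their adjusted p was 2.1e-05 and 0.028, and 0.95 and 0.23 with an estimated correlation. With the block 5 more lists passed under siRARA, namely G2 and M phase, retinoid synthesis and receptors, cholesterol synthesis, sarcomere, and smooth muscle and pericyte (adjusted p between 0.035 and 0.039). Under siRARB 1 more passed with it, retinoid synthesis and receptors (0.035).

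Under both siRNAs 10 further lists passed, and no gene of any of them did (0 adjusted over the list alone for each). The S phase (median log2 change 0.16), G2 and M phase (0.22), histone (0.14), endothelial (1.28) and endoderm and liver lists (0.50) were higher. The sarcomere (-0.14), fatty acid oxidation (-0.06), oxidative phosphorylation (-0.08), cholesterol synthesis (-0.23) and immediate early and heat shock lists (-0.17) were lower. Their adjusted p was at most 0.016, and 0.27 to 0.57 with an estimated correlation. The endothelial genes were high in 1 library, Am80 under both siRNAs replicate 1. There CDH5, the endothelial cadherin, stood at 1024, against a median of 29.7 and a highest value of 141 in the other 23 libraries, and PECAM1, which encodes the CD31 used for negative sorting, at 502 against 30.9 and 93.9. Without that library 4 of the 11 lists passed, namely retinoic acid targets (median 0.65), G2 and M phase (0.13), sarcomere (-0.30) and immediate early and heat shock (-0.18), with adjusted p = 2.5e-12, 0.0027, 4.7e-06 and 0.0051. The endothelial list stood at 0.09 (adjusted p = 0.71). In the order of their numbers the pairs of libraries, the first of which holds that library, had sarcomere medians of -0.0779, 0.251 and -0.624. Their G2 and M phase medians were -0.0633, 0.179 and 0.591. With the block and without that library the S phase (2.2e-07) and cholesterol lists (1.5e-06) passed too and the immediate early and heat shock list did not (0.066). The retinoic acid targets then had a median of 0.29. In that fit the interferon response (median -0.50, 9.9e-07), mitochondrially encoded (0.12, 0.0059), fibroblast (-0.17, 0.0062) and smooth muscle lists (-0.24, 0.019) passed as well. With the block the fibroblast, smooth muscle and pluripotent lists passed as well in the fit to all libraries (adjusted p = 0.015, 0.015 and 0.017).

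With the block 134 genes rose and 32 fell with Am80 under siRARA, and 187 and 43 under siRARB, and DESeq2 called 52 and 77. Fits to the 6 libraries of 1 siRNA called 0 genes under siRARA (465 at an unadjusted p under 0.05) and 12 under siRARB, while edgeR on all libraries called 23 under siRARA. The 465 are also fewer than chance alone would give among 16304 tested genes. Under siRARA the counts that rose were 6 without DMSO replicate 1, 36 (with 6 that fell) without Am80 replicate 1, 6 without DMSO replicate 2, 3 without Am80 replicate 2, 4 without DMSO replicate 3 and 3 without Am80 replicate 3. Under siRARB they were 17 without Am80 replicate 1, 20 without DMSO replicate 2, 14 without Am80 replicate 2, 18 without DMSO replicate 3 and 19 without Am80 replicate 3.

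**Figure D2:**
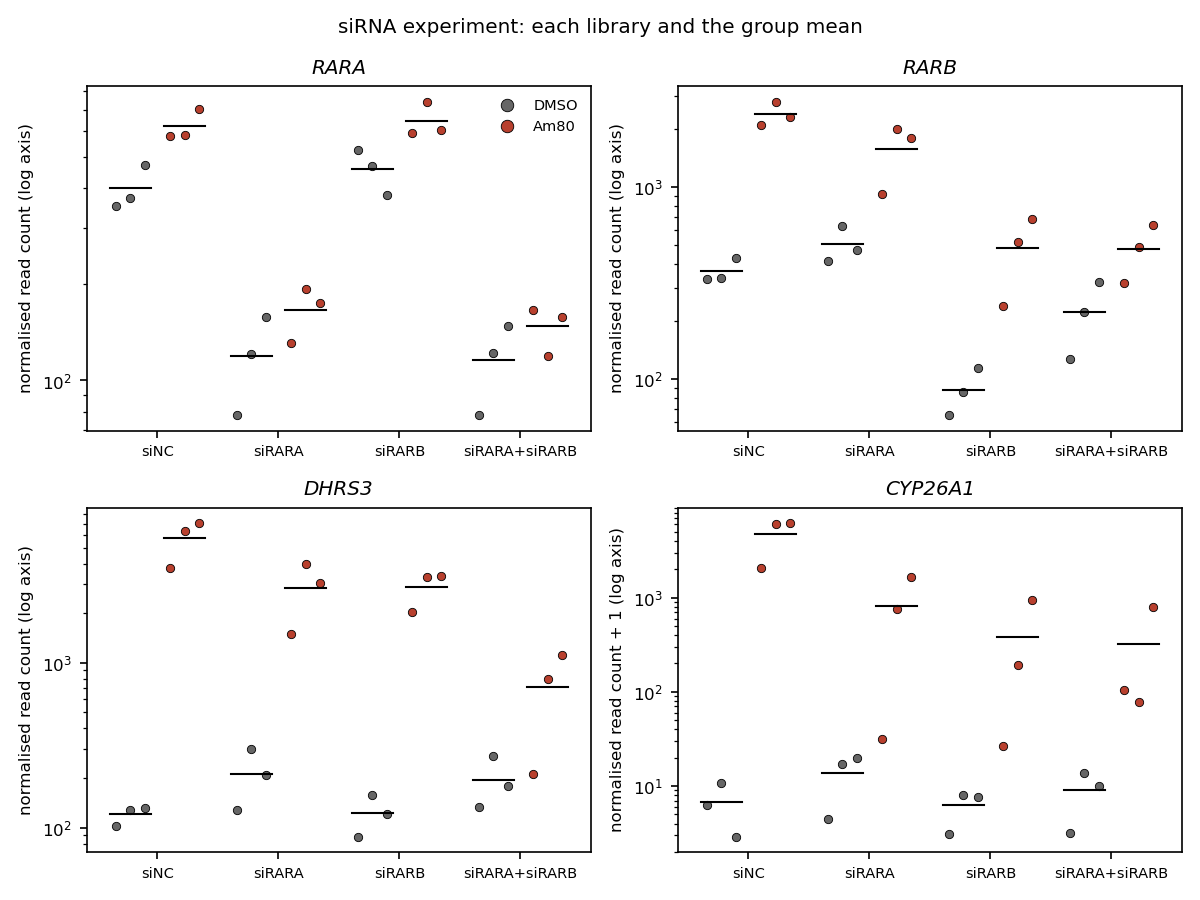
Normalised read counts on a log axis for RARA, RARB, DHRS3 and CYP26A1 (plus 1) in the 24 libraries of the siRNA experiment, by siRNA, with DMSO in grey and Am80 in red, where points are libraries (3 per group) and lines are group means. The mean of DHRS3 with Am80 is 5714 under siNC, 2842 under siRARA, 2891 under siRARB and 708 under both siRNAs.

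Whether the receptor siRNAs changed the response to Am80 was tested as the difference of the Am80 effect from that under siNC (n = 3 per group). The 18 retinoic acid targets responded less under siRARA, siRARB and both siRNAs, with median differences of -0.92, -0.57 and -0.98 log2. The adjusted p was 1.1e-09, 9.2e-06 and 1.9e-10, and 0.58, 0.26 and 0.27 with an estimated correlation (0.017, 0.10 and 0.020 with the block as well). Over all genes under both siRNAs MEGF6 (difference -2.31 log2, adjusted p = 0.030) and ERVFRD-1, an endogenous retroviral envelope gene chosen after its values were seen (-5.94, adjusted p = 0.019), responded less, the latter from a mean of 0.211 ± 0.365 under siNC in DMSO. DHRS3 (-3.90), CDKN2B (-2.44), CYP26B1 (-5.89) and RARB (-1.58) did not pass (adjusted p = 0.060, 0.11, 0.22 and 0.83) and did with the block (1.2e-05, 0.00097, 0.0053 and 0.0095). Of the retinoic acid targets 0 passed over all genes and 8 did adjusted over the list alone. The S phase, G2 and M phase and histone lists responded less under each siRNA, with medians of -0.26, -0.38 and -0.32 under siRARA, -0.43, -0.45 and -0.46 under siRARB and -0.28, -0.25 and -0.29 under both. For the sarcomere and calcium handling lists, which Am80 lowered under siNC, the differences were 0.34 and 0.34 under siRARA, 0.43 and 0.41 under siRARB and 0.41 and 0.33 under both. Both lists were already lower in DMSO under each receptor siRNA than under siNC, and these differences share the siNC libraries. Without Am80 under both siRNAs replicate 1 the sarcomere difference under both was 0.22 and did not pass (adjusted p = 0.14, and 0.012 with the block). With all libraries, for these 15 tests the adjusted p was at most 0.011, and 0.26 to 0.88 with an estimated correlation, and no gene in them passed over all genes.

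As single genes 0 differed under siRARA (378 at an unadjusted p under 0.05) or siRARB (248), with limma, edgeR and DESeq2 alike, and 1 did under siRARB without the filter. Under both siRNAs 2 differed (647 at an unadjusted p under 0.05; 238 with the block, 40 with DESeq2, 0 with edgeR, 0 with a minimum mean of 50 and 0 in the fit to the 12 libraries compared). The counts at an unadjusted p under 0.05 (378, 248 and 647) are below the share of 0.05 of 16304 tested genes that chance alone would give. With the block they were 1180, 877 and 1835. They are therefore no sign of leftover effects, and a count of 0 is no evidence that the effect was unchanged. Leaving out libraries under both siRNAs gave 0 for replicates 1, 5 for DMSO replicate 3, 6 for Am80 replicate 3, 1 for DMSO replicate 2 and 4 for Am80 replicate 2. Leaving out siNC libraries gave 6 for DMSO replicate 1, 3 for Am80 replicate 1, 0 for replicates 2 and 4 for replicates 3. Neither gene passed without replicate 1 of either treatment under both siRNAs or without siNC replicate 2 of either treatment, nor did MEGF6 without DMSO replicate 2 under both siRNAs (differences of -2.31 to -2.06 for MEGF6 and -5.98 to -5.75 for ERVFRD-1).

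The 4 sets of genes from the other experiments also moved most under siNC. The 945 Am80-raised genes had a median log2 change with Am80 of 0.40 under siNC, 0.17 under siRARA, 0.10 under siRARB and 0.10 under both siRNAs, and the 586 Am80-lowered genes -0.34, -0.16, -0.14 and -0.08. The differences from siNC were -0.22, -0.27 and -0.27 for the raised set (adjusted p with an estimated correlation = 0.0012, 1.4e-04 and 8.7e-05) and 0.20, 0.20 and 0.28 for the lowered set (0.0077, 0.0021 and 0.0010). In DMSO the lowered set was already lower than under siNC under siRARA (median -0.19, adjusted p = 0.00044) and both siRNAs (-0.15, 0.0013). So was the Red-high set under siRARA, siRARB and both (-0.15, -0.15 and -0.16, adjusted p = 0.0046, 1.4e-04 and 0.0013), and with an estimated correlation the adjusted p of these 5 tests was 0.20 to 0.47. The 1506 Green-high genes had medians of 0.21, 0.07, 0.01 and 0.11, and the 889 Red-high genes -0.20, -0.09, -0.03 and -0.07. Without Am80 under both siRNAs replicate 1 the last values were 0.04 and -0.03, and the Red-high set did not pass there (adjusted p = 0.11, and 0.00027 with the block). The differences of the Green-high set were -0.14, -0.21 and -0.12 (adjusted p = 3.1e-06, 1.5e-15 and 0.00044, and 0.16, 0.027 and 0.28 with an estimated correlation). Those of the Red-high set were 0.13, 0.18 and 0.15 (0.00024, 2.2e-09 and 0.00044, and 0.16, 0.028 and 0.23 with an estimated correlation). Under siRARB neither the Green-high nor the Red-high set passed with Am80 (adjusted p = 0.58 for both).

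**Figure D3:**
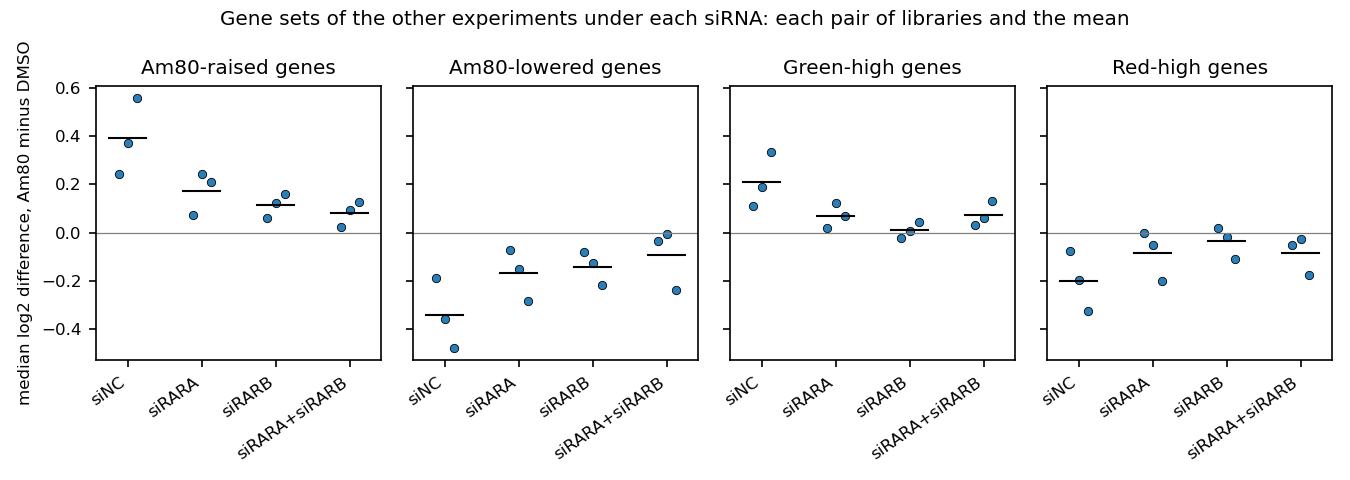
Median log2 difference between Am80 and DMSO over the genes of 4 sets found in the FUCCI and sorted experiments, by siRNA, where points are pairs of libraries with the same number (3 per siRNA) and lines are their means. The 3 pairs of the Am80-raised set lie between 0.244 and 0.557 under siNC and between 0.061 and 0.160 under siRARB.

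The receptor siRNAs were compared with siNC in DMSO to measure the knockdown and its effect without the agonist. RARA fell from 398 ± 65.3 (n = 3) to 119 ± 39.8 (n = 3) under siRARA (log2 change -1.78) and to 116 ± 35.6 (n = 3) under both siRNAs (-1.80). RARB fell from 366 ± 55.2 to 88.2 ± 24.7 (n = 3) under siRARB (-2.07). Under both siRNAs RARB stood at 224 ± 97.2 and did not pass (-0.79; adjusted p = 0.30, and 0.015 with the block), and the change was -0.44 without replicate 1 under both siRNAs and -1.10 without replicate 3. Without DMSO siRARB replicate 1 the fall of RARB under siRARB no longer passed (-1.87). With Am80, RARB stood at 242, 518 and 680 in siRARB replicates 1, 2 and 3, against 2116, 2790 and 2334 under siNC. In replicates 2 and 3 this was above the siNC mean in DMSO.

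Under siRARA the contractile genes were lower. Of 25 sarcomere genes 14 fell (20 adjusted over the list alone, median log2 change -1.14, adjusted p = 1.2e-16, and 0.12 with an estimated correlation). MYH6, the atrial and embryonic heavy chain of cardiac myosin, fell from 102600 ± 32340 (n = 3) to 27140 ± 10560 (n = 3). MYBPC3, cardiac myosin-binding protein C, fell from 4228 ± 634 to 1218 ± 181, and LDB3, a Z disc protein, from 1077 ± 221 to 298 ± 69.3. Calcium handling and ion channel genes (3 of 21 fell, 4 adjusted over the list alone), smooth muscle genes (1 of 12, 1), fibroblast and matrix genes (0 of 18, 0) and histone genes (1 of 28, 1) were lower as lists. KCNH2, a repolarising potassium channel, fell from 1517 ± 410 to 791 ± 142. Pluripotent genes were higher (1 of 7 rose, 4 with 1 that fell). The adjusted p of these 5 lists was 0.00013 to 0.040, and 0.20 to 0.67 with an estimated correlation. CCNB2, cyclin B2, fell from 1285 ± 392 to 520 ± 88.6, but the G2 and M phase list did not pass (adjusted p = 0.96). MICB, a ligand of a receptor on natural killer cells, rose from 188 ± 50.9 to 794 ± 176. With the block 5 more lists passed, namely the interferon response (adjusted p = 0.19, and 0.011 with it), the atrial (0.0020), the ventricular (0.0013), the epicardial (0.028) and the endoderm and liver lists (0.046).

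Under siRARB APAF1, the scaffold of the apoptosome, fell from 1096 ± 123 (n = 3) to 463 ± 99.7 (n = 3), and BOD1, a kinetochore protein, rose from 848 ± 213 to 1807 ± 119. Of 19 genes of the integrated stress and unfolded protein response 2 rose (5 adjusted over the list alone, median log2 change 0.39, adjusted p = 7.2e-05). HSPA5, the chaperone BiP, rose from 6637 ± 529.6 to 11080 ± 1102, a call lost without DMSO siRARB replicate 1 (log2 change 0.66). The interferon response (0 of 21 rose, 12 with the block, median 1.18), YAP targets (0 of 19, 0.35), p53 targets (0 of 21, 0.20) and cholesterol synthesis (1 of 21, 0.15) were higher as lists, with adjusted p = 0.00075, 0.029, 0.018 and 0.047. The sarcomere (0 of 25 fell, median -0.15), calcium handling (0 of 21, -0.40), fatty acid oxidation (0 of 25, -0.13), oxidative phosphorylation (0 of 36, -0.06), fibroblast (1 of 18, -0.30) and endoderm and liver lists (0 of 12, -1.16) were lower, with adjusted p of 0.0051 to 0.044. Of the liver genes, ALB was lower under siRARB in replicates 2 (124 against 640.2) and 3 (86.1 against 2582), while in replicate 1 ALB (208 against 75.8) and AFP (324 against 230.5) were higher. The same siNC libraries enter the comparisons under siRARA and both siRNAs, the Am80 effect under siNC and the differences from it. Under siNC, ALB was lower with Am80 in replicates 2 (43.5 against 640.2) and 3 (399 against 2582) but not in replicate 1 (88.8 against 75.8). Adjusted over the list alone, 1 gene each of the cholesterol, fibroblast and sarcomere lists passed and 0 of these other lists. With an estimated correlation the adjusted p of these 11 lists was 0.61 to 0.75. With the block the retinoic acid targets (adjusted p = 0.085, and 0.0076 with it), histone (0.046), atrial (0.046), ventricular (0.024) and pluripotent lists (0.032) passed too.

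Under both siRNAs 7 of 25 sarcomere genes fell (15 adjusted over the list alone, median -0.79, adjusted p = 2.0e-12, and 0.16 with an estimated correlation). MYBPC3 fell to 1598 ± 531 (n = 3) and LDB3 to 378 ± 142. MICB rose to 776 ± 208, and TGFBR2, a receptor of transforming growth factor beta, fell from 1072 ± 214 to 352 ± 63.9. The calcium handling (3 of 21 fell, 3 adjusted over the list alone), smooth muscle (1 of 12, 1), fibroblast (0 of 18, 0), ventricular (0 of 14, 0), histone (0 of 28, 0) and endoderm and liver lists (0 of 12, 0) were lower. The cholesterol synthesis (2 of 21 rose, 2) and pluripotent lists (1 of 7, 6 with 1 that fell) were higher. Their adjusted p was 0.0020 to 0.038, and 0.12 to 0.77 with an estimated correlation. The atrial list passed with the block only (adjusted p = 0.095, and 0.0048 with it).

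In DMSO 402 genes rose and 596 fell under siRARA (1615 and 1681 with the block; 673 and 457 with equal library totals), 85 and 56 under siRARB (979 and 618; 59 and 77) and 251 and 358 under both siRNAs (1374 and 1283; 372 and 296). The fits to the 6 libraries of the 2 groups called 0 genes in each of the 3, and none of the calls named here passed in them, RARA and RARB included. Without the filter 615, 87 and 379 genes passed, and DESeq2 called 425 under siRARB and 1059 under both. The counts under siRARA were 183 and 295 without siRARA replicate 1, 203 and 393 without siRARA replicate 2, 257 and 449 without siRARA replicate 3 and 204 and 339 without siNC replicate 2. Under siRARB they were 19 and 10 without siRARB replicate 1, 32 and 21 without siRARB replicate 2 and 39 and 16 without siNC replicate 2. Under both they were 78 and 131, 92 and 181, and 138 and 219 without the corresponding libraries.

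Many genes that were lower under a receptor siRNA shared a short sequence in their 3′ UTRs. Of 15639 heptamers, AGAACTC went with the lowest changes under siRARA in DMSO. The 1179 genes that carry it were lower by a mean of 0.217 log2 than the others (z = -18.1), and GAACTCA, which overlaps it by 6 bases, followed (z = -16.2). The same pair ranked lowest with Am80 (z = -16.7 and -14.6) and under both siRNAs (-17.7 in DMSO and -13.1 with Am80 for AGAACTC), whereas under siRARB AGAACTC had z = -0.322 and -0.0866. Under siRARB the lowest pair was AAAGCTC (mean shift -0.108, z = -11.0 in DMSO and -9.41 with Am80) and AAGCTCA (z = -9.54 and -7.30), and AAAGCTC had z = -4.26 and -1.23 under both siRNAs. Of the 559 genes with a searched UTR that fell under siRARA, 261 (46.7%) carried AGAACTC or GAACTCA, against 15.2% of the 11683 genes searched and 7.19% of those that rose. Of the 55 that fell under siRARB 29 (52.7%) carried AAAGCTC or AAGCTCA, against 2.44% of those that rose, and of the 345 that fell under both 177 (51.3%) carried the siRARA pair. MYBPC3, LDB3, CCNB2, TGFBR2 and RARA itself carry a site of the siRARA pair and APAF1 carries 1 of the siRARB pair, while MYH6 and KCNH2 carry none. On 20 permutations the highest absolute z was 5.02. Among the sequences that went with higher levels were GCAACCT under siRARA (z = 6.23) and both siRNAs (5.95) and TGACGTA under siRARB (7.08) and both siRNAs (5.79). GCAACCA, which overlaps GCAACCT, had z = 4.74 under siRARA and 4.84 under siRARB, both below the highest value on permutations. All of these comparisons share the siNC libraries. ATCGTCC went with higher levels with Am80 under both siRNAs (7.15). That comparison holds Am80 under both siRNAs replicate 1, the library high in endothelial genes, and the scan was not repeated without it. The 136 genes with the site had a median log2 change of 0.0253 against -0.0116 in the others. The siRNAs are the same on both sides there, so a z beyond 5.02 can arise without a difference of siRNA. The sequences of the siRNAs are not given, and the comparison of the leading pairs across siRNAs and treatments was chosen after the scan. The shares under siRARA and siRARB were counted in the comparisons that gave the pairs, without adjustment for UTR length.

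**Figure D4:**
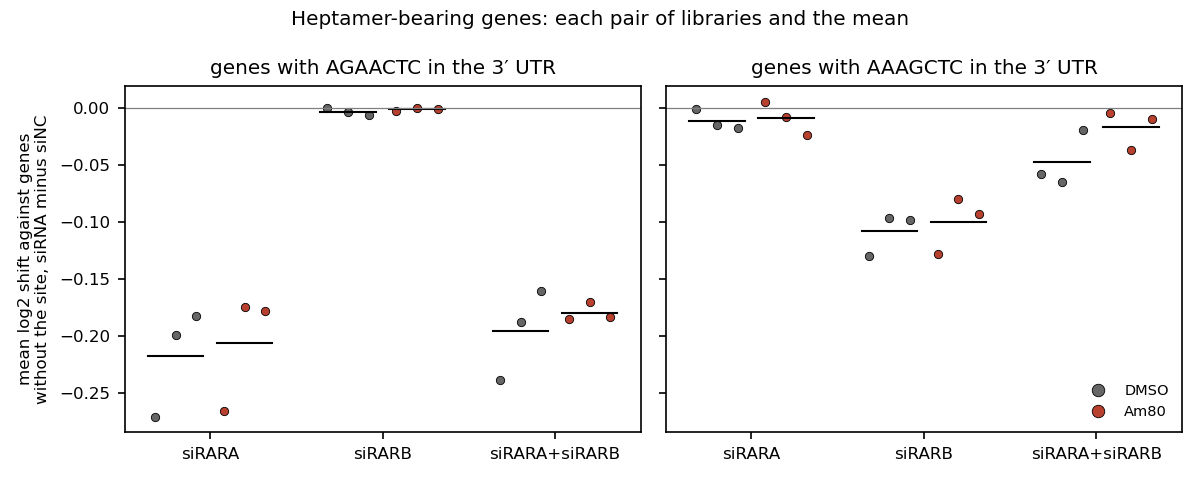
Mean log2 shift, siRNA minus siNC, of genes with AGAACTC or with AAAGCTC in the 3′ UTR against the other genes, by siRNA, with DMSO in grey and Am80 in red, where points are pairs of libraries with the same number (3 per group) and lines are their means. For AGAACTC the 3 pairs in DMSO lie between -0.270 and -0.182 under siRARA and between -0.00605 and 0.000194 under siRARB.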

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

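The tests of epithelial, cardiac and endothelial genes, of sarcomere genes without a site, and the tests of lists and sets without Am80 under both siRNAs replicate 1 were chosen after the results were seen, while the sequence scan, the test of the Am80-raised genes and the splits of the libraries were planned before theirs.

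The effect of Am80 differed between a receptor siRNA and the control siRNA in 41 lists or sets and 2 genes, by the test of the difference itself. With an estimated correlation none of the 29 lists passed, and of the 12 sets the Green-high and Red-high sets under siRARA and both siRNAs did not. With the block 8, 10 and 15 lists passed under siRARA, siRARB and both siRNAs, where 6, 11 and 12 did without it. All values are median differences of the log2 effect from that under siNC. Under siRARA they were -0.921 for retinoic acid targets, -0.259 for S phase, -0.380 for G2 and M phase, -0.324 for histones, 0.344 for sarcomere and 0.336 for calcium handling. For the gene sets under siRARA they were -0.137 (Green-high), 0.126 (Red-high), -0.224 (Am80-raised) and 0.202 (Am80-lowered).

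Under siRARB the differences were -0.573 for retinoic acid targets, -0.427 for S phase, -0.451 for G2 and M phase, -0.309 for G1 cyclins and E2F, -0.460 for histones, 0.435 for sarcomere and 0.414 for calcium handling. They were 0.0999 for fatty acid oxidation, 0.0393 for oxidative phosphorylation (adjusted p = 0.044, and 0.059 with the block), -0.214 for the integrated stress and unfolded protein response and 0.309 for smooth muscle. The gene sets stood at -0.207 (Green-high), 0.184 (Red-high), -0.267 (Am80-raised) and 0.199 (Am80-lowered).

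Under both siRNAs the single genes were ERVFRD-1 (-5.94) and MEGF6 (-2.31). The lists stood at -0.979 for retinoic acid targets, -0.278 for S phase, -0.252 for G2 and M phase, -0.294 for G1 cyclins and E2F, -0.291 for histones, 0.413 for sarcomere, 0.334 for calcium handling, -0.207 for cholesterol synthesis, -0.304 for immediate early and heat shock, 1.10 for endothelial, 0.994 for endoderm and liver and 0.627 for neural. The sets stood at -0.118 (Green-high), 0.149 (Red-high), -0.275 (Am80-raised) and 0.280 (Am80-lowered). Without the library Am80 under both siRNAs replicate 1, 7 of the 12 lists and all 4 sets passed, and the sarcomere, cholesterol, endothelial, endoderm and liver, and neural lists did not. With the block as well, the sarcomere (adjusted p = 0.012) and cholesterol lists (0.00026) passed without that library and the other 3 did not. With an estimated correlation no list difference passed under any receptor siRNA, and with the block as well only the retinoic acid targets did, under siRARA (adjusted p = 0.017) and both siRNAs (0.020).

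For each difference 100 splits of the 12 libraries behind it were drawn. Under both siRNAs 10 of them gave at least as many genes as the real 2 (highest other 2369). Chance was not excluded for that count, and these splits could not exclude it. These splits ignore the replicate number, 16 of them part as many pairs as the real one (highest other among these 2369), and with the block the real count was 238. A real count of 0 is reached by every split, so the 100 of 100 splits under siRARA (highest other 1514) and under siRARB (1095) say nothing about chance. The splits exchange the siRNA names in Am80 and in DMSO separately. A split that exchanges them in Am80 but not in DMSO turns the difference into an effect of the siRNA itself. For that effect 609 genes passed in DMSO under both siRNAs. High counts can arise in this way, which was not tested, so the splits are no measure of chance for a difference.

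The endothelial genes that were higher with Am80 under both siRNAs were the first pattern weighed. An effect of Am80 needs them to be higher in every pair, but the median Am80 minus DMSO difference of the 13 genes was 3.51 in the pair numbered 1, 0.0143 in the pair numbered 2 and -0.00298 in the pair numbered 3. RNA of other cells in 1 library may account for it: 10 of the 13 genes had their highest value of the 24 libraries in Am80 under both siRNAs replicate 1, among them CDH5 (1024), PLVAP (735), TIE1 (700) and PECAM1 (502). That library also held the highest CDH1 (681, against at most 143 in the others). Sorting against CD31, the product of PECAM1, should remove endothelial cells, and whether this library was sorted differently is not known.

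The genes that were lower under siRARA were the second pattern. Unintended targets of the siRARA siRNA are a candidate explanation for part of it: the lowest z of the scan was -18.1 (AGAACTC), against at most 5.02 in permutations, and 261 of 559 lower genes carried AGAACTC or GAACTCA. The pair was picked in this same comparison, so that share is no separate support. In the Am80 libraries AGAACTC had z = -16.7 under siRARA. Matches to AGAACTC or GAACTCA do not extend to the sarcomere genes as a group, since the 19 of 23 searched that lack both had a median of -1.13. These genes may carry related heptamers that also went with lower levels, such as GAACTCT (z = -11.5) and TGAACTC (z = -10.3). Other direct matches are therefore not excluded for them. Loss of receptor signalling in DMSO would lower the genes that Am80 raises and raise those it lowers, if the receptors were active there. In DMSO under siNC the targets CYP26A1 and CYP26B1, though not RARB or DHRS3, were barely detected. There may be little signalling to lose, so this test cannot decide the question. The criterion set in advance asked for lower Am80-raised genes with an adjusted p under 0.05, and it was not met. The 945 Am80-raised genes went both ways (412 higher, 533 lower, median -0.0571, adjusted p = 0.20). The 586 Am80-lowered genes were lower (-0.189, adjusted p = 0.00044, and 0.20 with an estimated correlation), where the prediction was higher. A loss of signalling is not excluded. Effects downstream of the unintended targets were not tested.

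Lower sarcomere genes and higher CDH1 and EPCAM in Green than in Red were the third pattern. A lower share of cardiomyocytes alone, with the mix of the other cells unchanged, would raise the genes of all other cell types. The endoderm and liver list, which did not pass with an estimated correlation, had a median of -4.46 instead. The other part of that prediction was met: 12 of 12 cardiac markers were lower (median -1.58), about as much as the sarcomere list. A lower share together with a changed mix of other cells is not excluded. Epithelial cells among the Green cells may account for part of the pattern: all 20 epithelial markers were higher (median 3.67, range 1.22 to 4.95), CDH1 at 9766 ± 3363 in Green. Sorting for CD172a/b would remove epithelial cells that lack it, and none of the other sorted markers is specific to epithelium. Liver genes such as AFP (21040 ± 4578 in Red) point the other way, and a difference between cardiomyocytes in and out of the cycle, which the design names, stays open and untested.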

How the results depend on the processing

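The tests of lists and sets without Am80 under both siRNAs replicate 1, chosen for its endothelial genes, the fit without it that had the block, chosen because it followed its number least, the tests of sets with the block and the estimated correlation of lists together with the block were added after the data were seen. Of 1558 values of the 118 genes named with a comparison, 1469 kept their direction and their side of the threshold, 57 no longer passed, 32 passed where they had not, and 0 changed sign. A pseudocount of 8 and equal library totals left each total of genes that passed within 1.5 times its value, though equal library totals moved some counts of 1 direction by more (224 to 371 lower in Green than in White, 402 to 673 higher under siRARA in DMSO). With the block the counts were 7915 (Green against Red), 2590 (White against Red), 3688 (Green against White), 6008 (sorted), 1707 (Am80 under siNC), 166 (siRARA), 230 (siRARB), 238 (difference under both siRNAs), and 3296, 1597 and 2657 (siRARA, siRARB and both in DMSO), and RARB passed under both siRNAs (-0.793). The block takes out the spread that libraries of 1 number share. The main fit leaves that spread in, so genes that did not pass there are not shown to be unchanged. With DESeq2 they were 1099 (White against Red), 1960 (Green against White), 503, 52, 77 and 2 (Am80 under siNC, siRARA, siRARB and both), 40 (difference under both) and 425 and 1059 (siRARB and both in DMSO). With edgeR they were 23 (Am80 under siRARA) and 0 (difference under both, which was also 0 with a minimum mean of 50). Without the filter they were 615, 87 and 379 (siRARA, siRARB and both in DMSO), 1 (Am80 under both) and 1 (difference under siRARB). For DESeq2, edgeR and the filters the cause was not tested.

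With only the libraries of the groups compared, which leaves fewer samples to estimate the spread, the counts were 25, 0 and 12 (Am80 under siNC, siRARA and siRARB), 0 (difference under both) and 0, 0 and 0 (the 3 siRNAs in DMSO), and RARA (-1.78 under siRARA, -1.80 under both) and RARB (-2.07 under siRARB) no longer passed. With 1 library left out, which also leaves fewer samples, the counts ran from 1057 to 3741 (Green against Red), 109 to 278 (White against Red), 467 to 630 (Green against White), 767 to 1936 (sorted), 119 to 322, 3 to 42, 14 to 28 and 0 to 3 (Am80 under siNC, siRARA, siRARB and both), 0 to 152 (difference under both), 478 to 1021, 29 to 177 and 209 to 569 (siRARA, siRARB and both in DMSO), and RARB under siRARB from -2.27 to -1.87, where it no longer passed without DMSO siRARB replicate 1 (-1.87). The 3 and the 152 come from the fit without Am80 under both siRNAs replicate 1 that also had the block. A FUCCI group left with 1 library is taken to vary like the others. Of the list tests 140 of 407 passed, 1 with an estimated correlation and 6 with the block as well, and of the 48 tests of sets 39, 17 and 16. Without Am80 under both siRNAs replicate 1, 4 instead of 11 lists passed for Am80 under both siRNAs and 7 instead of 12 for its difference from siNC; with the block as well, 5 of these 11 and 9 of these 12 passed. In the simulation small changes were often missed: a change of 1 log2 was recovered in 10% of the simulated genes for Green against Red and 61% for Am80 under siNC. It had 200 changed genes and no effect shared by a replicate number, so these shares need not hold for the real data.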

Other observations

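The genes named in this part were chosen after their values were seen, and no test was, since the splits of the libraries were planned.

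In the sorted experiment THBD, the anticoagulant receptor thrombomodulin, rose from 36.8 ± 3.01 (n = 3) to 7412 ± 1243 (n = 3) in the libraries titled Am80. CALB2, the calcium-binding protein calretinin, rose from 4.93 ± 3.25 to 1647 ± 670 there, and from 28.8 ± 10.7 (n = 3) to 756 ± 375 (n = 3) under siNC. Under siNC PTGIS, prostacyclin synthase, rose from 69.5 ± 26.5 to 2522 ± 1026 and ADM, the vasodilator peptide adrenomedullin, from 413 ± 103 to 1333 ± 139. NRIP1, a corepressor of nuclear receptors, rose from 1552 ± 101 to 4693 ± 541. The growth factor gene TGFA fell from 927 ± 416 to 77.9 ± 69.0 in the sorted experiment, and the adhesion gene NCAM1 fell from 1990 ± 222 to 1276 ± 20.6 under siNC. In the fit to the 6 libraries under siNC alone, ADM and NCAM1 did not pass.

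Under siRARA in DMSO PODXL2, a sialomucin, rose from 99.3 ± 31.1 (n = 3) to 331 ± 28.0 (n = 3) and DNER, a Notch ligand, from 23.6 ± 5.43 to 97.2 ± 21.0, while PKM, pyruvate kinase, fell from 30260 ± 260 to 20400 ± 3131. Under both siRNAs TXNIP, an inhibitor of thioredoxin, fell from 5498 ± 1922 (n = 3) to 1595 ± 342 (n = 3). None of these 4 passed in fits to the 6 libraries of the 2 groups alone.

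With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes as observed in the sorted experiment (1671, highest other 0), for Am80 under siNC (260, highest other 184), siRARA (15, highest other 0) and siRARB (33, highest other 1), and for siRARA (998, highest other 26), siRARB (141, highest other 0) and both siRNAs (609, highest other 0) against siNC in DMSO. For Am80 under both siRNAs all 10 splits gave at least the real count of 0, and none gave more. The numbers pair the libraries, and among the 4 splits that part all 3 pairs the highest other count was 0 in each comparison. The splits that gave 184 and 26 part 1 pair and leave each of the other 2 pairs together on 1 side.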
